A study of Mus musculus with 8 samples.

How the data were processed

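Total RNA was sequenced from cultured Eµ-Myc mouse lymphoma cells in 4 groups of 2 libraries each: sh-Ren without doxycycline, and sh-Ren, sh-EiF5A and sh-Dhps with doxycycline at 0.9 µg/mL for 72 hours, per the labels' protocols. RNA was extracted with a miRNeasy kit, treated with DNase and made into libraries with the Epicentre ScriptSeq Complete Gold kit, a directional kit that removes ribosomal RNA. The authors deposited a table of raw read counts per gene symbol, 1 column per library. Per the submitters' processing notes, bcl2fastq 2.20.0.422, TopHat2 2.0.13 and HTSeq were used, with the builds mm10 and GRCh38 named. The HTSeq version, the strand setting, the gene annotation and the role of each build were not given in the sources used here. The deposited counts were used as they stand, with no sample left out. Groups were taken from the labels, which do not say whether the 2 libraries of a group came from separate cultures.

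The table held 16688 genes. Symbols were matched to the GENCODE M21 annotation of GRCm38 for coordinates: 15669 matched directly, 828 through older names and 191 not at all. Of the matched genes, 4936 had exons that overlapped an exon of a gene on the other strand, and 11561 had none. Overlapped genes are reported as uncertain, because the strand setting is unknown. If reads were counted on the strand opposite to the transcript, the counts of genes without overlap would be uncertain as well. Ribosomal protein and histone genes are also uncertain, since they share reads with near-identical copies or pseudogenes.

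Library totals ran from 513501 to 2151559 counts. Without the genes Rn45s and Lars2, they ran from 269316 to 1057656. At this depth a group total of 0 was read against a floor of 3 counts over the group, and folds against such a group are given as lower bounds. Where a group held 1 to 3 counts, the ratio is given with its exact 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. CPM is the scaled count of edgeR, computed with TMM library sizes.

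Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, on 8459 genes kept by its filter on low counts, with TMM scaling and all 8 libraries in a single fit with 4 residual degrees of freedom and no covariates. The common biological coefficient of variation was 0.19. P-values were two-sided and adjusted with the Benjamini-Hochberg method, at a threshold of 0.05. All adjusted p-values for genes come from this test unless another tool is named. Standard errors of log2 fold changes were taken as the size of the change divided by the square root of F. P-values measure only the spread between these libraries. The comparisons were sh-Ren with against without doxycycline, sh-EiF5A and sh-Dhps each against sh-Ren with doxycycline, and sh-Dhps against sh-EiF5A. Genes changed the same way in both depletions were counted beside 50 simulated draws of unchanged groups against the same controls.

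Before the data were examined, 27 gene lists were fixed, and the 22 with at least 5 tested members were tested with camera from limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of each comparison. The lists were: polyamine and hypusine pathway, MYC-induced growth genes, ribosome biogenesis, cytosolic ribosomal proteins, translation factors and tRNA synthetases, G1/S and DNA replication, G2/M and mitosis, p53 targets, integrated stress response, unfolded protein response, interferon response, nuclear-encoded oxidative phosphorylation, mitochondrial ribosome and translation, mitochondrial chaperones and proteases, glycolysis and hypoxia response, cholesterol synthesis, lysosome and autophagy, BCL2 family, replication-dependent histones, and genes of early B, mature B, plasma, T and natural killer, myeloid, erythroid and fibroblast cells. A list of mitochondrially encoded genes had 0 members in the table. The T and natural killer, myeloid, erythroid and fibroblast lists had fewer than 5 tested members and are given as summed CPM only. Camera with an estimated correlation was run as an alternative, and so was fry, which tests a list against no change and not against other genes.

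The genes named were set by a rule fixed before the data were examined. It takes Eif5a, Dhps, Myc, E2f1 and Odc1 always. It then takes the 8 highest and 8 lowest log2 fold changes among changed genes with a mean of at least 5 CPM and no overlap between the groups' libraries, without predicted genes and pseudogenes. It adds up to 4 members with the lowest adjusted p from each list, of which any may be printed, and the 6 highest and 6 lowest genes changed the same way in both depletions. Repeating the second and last parts on genes without opposite-strand overlap was added after the data were seen. E2f1 did not pass the filter and was not tested. While the text was prepared, 8 genes with less stable calls were taken out of the printed set after their values were seen; the earlier set was then restored, and all counts of stable results refer to it.

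The alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and library-total scaling, no filter, a filter at 1 CPM in 4 libraries, robust spread, only the 4 libraries compared, the replicate number as a block, each library left out in turn, leaving out mitochondrial and histone genes, a minimum change of 1.2-fold, and other controls. After the data were seen, 3 were added: leaving out genes overlapped on the other strand, leaving out Rn45s and Lars2, and thinning every library to 269316 counts. A trend of fold change on exonic length and GC content was also removed as a test of an explanation.

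The fit was tested on simulated counts for the 8459 genes with 200 changed. At 2-fold, 29.9% of the changed genes were recovered in the doxycycline comparison, 16.4% for sh-EiF5A, 29.9% for sh-Dhps and 22.4% for sh-Dhps against sh-EiF5A. At 4-fold the shares were 74.6%, 64.2%, 86.6% and 70.1%, and at 8-fold 90.9%, 78.8%, 90.9% and 87.9%. Unchanged genes called numbered 3, 10, 7 and 5. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.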

Results

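RNA was sequenced from cells that, per the labels, are mouse Eµ-Myc lymphoma cells with an inducible short hairpin RNA, a B-lineage tumour driven by a Myc transgene. The hairpins were sh-EiF5A, sh-Dhps and sh-Ren, the last aimed at neither gene. Eif5a is a translation factor that carries the amino acid hypusine, and Dhps is the enzyme that starts hypusine synthesis from the polyamine spermidine. The series asks how depletion of each changes transcripts. Total counts were 649161 and 1044080 in sh-Ren without doxycycline, 982610 and 904639 in sh-Ren with doxycycline, 2151559 and 513501 in sh-EiF5A, and 1358957 and 1169596 in sh-Dhps. Between 10468 and 13525 genes were detected per library. Rn45s, the ribosomal RNA precursor, and Lars2 together took 81.35% and 47.55% of the counts in sh-EiF5A, 26.2% and 19.32% in sh-Ren with doxycycline, 18.54% and 20.21% without it, and 22.17% and 22.33% in sh-Dhps. Replicates correlated across genes at a Pearson r of 0.9403 (sh-Ren without doxycycline), 0.9389 (sh-Ren with), 0.8598 (sh-EiF5A) and 0.962 (sh-Dhps), where genes are not independent replicates.

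The targeted genes were lower in the libraries named for them. Eif5a (ENSMUSG00000078812.10, chromosome 11, 69916714 to 69921958, minus strand, GRCm38) held 294.2 and 416.7 CPM in sh-Ren without doxycycline, 637.3 and 373.6 with it, 37.86 and 20.75 in sh-EiF5A, and 611.2 and 526.3 in sh-Dhps. Against sh-Ren with doxycycline, with n = 2 libraries per group throughout, it fell 16.4-fold in sh-EiF5A (log2 fold change -4.04, SE 0.36, edgeR adjusted p = 7.95e-12). In sh-Dhps its change was 0.17 (SE 0.26, edgeR adjusted p = 0.703). Dhps (ENSMUSG00000060038.14, chromosome 8, 85071757 to 85075162, plus strand) held 32.17 and 23.93 CPM in sh-Ren without doxycycline, 29.01 and 21.3 with it, 26.5 and 53.36 in sh-EiF5A, and 6.439 and 7.984 in sh-Dhps. It fell 3.46-fold in sh-Dhps (log2 fold change -1.79, SE 0.46, edgeR adjusted p = 0.00436) and changed by 0.60 in sh-EiF5A (SE 0.46, edgeR adjusted p = 0.343). The Dhps value is uncertain, because it rests on 12 and 13 counts in sh-Dhps and because 128 bases of its exons overlap Wdr83 on the other strand, which held 3.219 and 3.685 CPM in sh-Dhps against 12.8 and 20.48. Its call ended without sh-Ren Dox+ replicate 1 (adjusted p = 0.064), without sh-Dhps Dox+ replicate 1 (0.0745), with library totals as the scaling (-1.66, 0.169) and at equal depth (-0.80, 0.547). Eif5a2, a close relative of Eif5a, held 46 counts in sh-Dhps and 3 in sh-Ren with doxycycline, a ratio of 10.5 (95% counting interval 3.38 to 52.8, edgeR adjusted p = 0.00982). That call ended without sh-Ren Dox+ replicate 2 (0.12), without sh-Dhps Dox+ replicate 1 (0.175), with DESeq2 (0.11) and with library totals (log2 fold change 3.42, 0.0622).

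**Figure D1:**
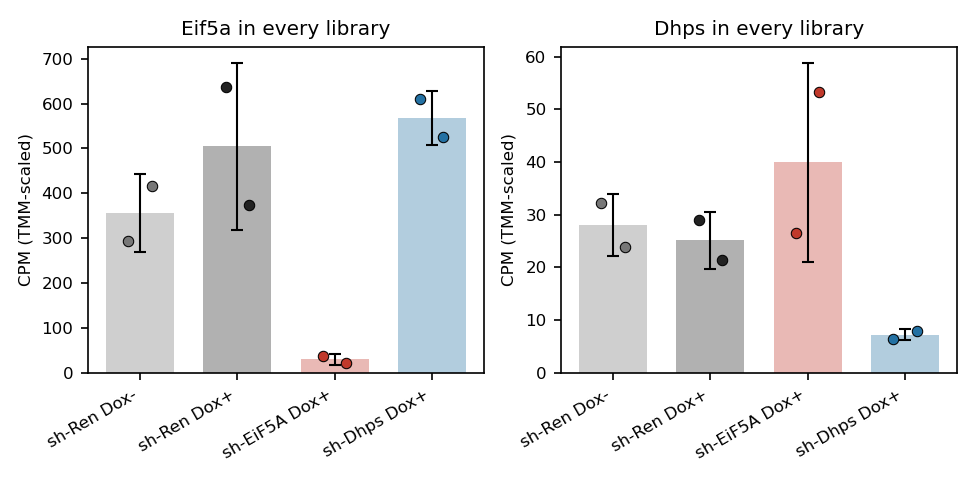
CPM of the target genes in each of the 8 libraries, with 2 libraries per group. Eif5a lay at 37.86 and 20.75 CPM in sh-EiF5A and between 294.2 and 637.3 elsewhere, and Dhps lay at 6.439 and 7.984 in sh-Dhps and between 21.3 and 53.36 elsewhere.

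Doxycycline moved no gene past the threshold in the libraries labelled sh-Ren. Most leukocyte genes were near 0 in these libraries, so they may not show what doxycycline does in the cells of the other groups. In simulated counts 29.9% of 2-fold changes were recovered in this comparison, so changes of that size could be missed. In edgeR 0 of 8459 genes passed, with 406 at an unadjusted p under 0.05 and 0 by DESeq2 and 0 by limma-voom. The smallest adjusted p, 0.0652, belonged to Mthfd2, a mitochondrial enzyme of folate metabolism, at a log2 fold change of 1.42 (SE 0.30). Asns, the asparagine synthetase, lay at 0.75 (SE 0.28, adjusted p = 1); both were chosen after their values were seen. Myc lay at 0.08 (SE 0.26) and Odc1, the first enzyme of polyamine synthesis, at 0.42 (SE 0.26), each with an adjusted p of 1. Of 31 tested integrated stress response genes, 0 passed over all genes and 1, Mthfd2, rose when adjusted over the list alone, with a list median of 0.242. Camera placed this list above other genes (adjusted p = 0.00544), and it had an adjusted p = 0.833 with an estimated correlation. The other 21 lists had camera adjusted p-values from 0.109 to 0.933. The list's call ended without sh-Ren Dox- replicate 1 (0.501), sh-Ren Dox+ replicate 2 (0.385), sh-Dhps Dox+ replicate 1 (0.0782) or sh-Dhps Dox+ replicate 2 (0.0557). The count of genes was 3 without sh-Ren Dox+ replicate 1, 1 without sh-Ren Dox+ replicate 2, 7 and 6 without sh-EiF5A Dox+ replicate 1 and 2, and 5 without either sh-Dhps library, and Mthfd2 passed without sh-EiF5A Dox+ replicate 1 (0.0136) or 2 (0.018), with the CPM filter (0.012), no filter (0.023) and robust spread (0.0475).

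In sh-EiF5A libraries, genes of early B cells, histones and ribosomal proteins were higher than in libraries labelled sh-Ren with doxycycline, and genes of glycolysis, cholesterol synthesis and mitosis were lower, by camera with its preset correlation. With an estimated correlation the early B call held (adjusted p = 0.0128) and the others ended (histones 0.107, ribosomal proteins 0.368, glycolysis 0.235, cholesterol synthesis 0.107, mitosis 0.288), and the ribosomal protein median became -0.478 when scaled by library totals, or 1.21 less the shift of all genes. Rag1, a recombinase of developing lymphocytes, was at least 155-fold higher (edgeR adjusted p = 3.85e-14), and Vpreb3, another gene of the early B cell list, at least 129-fold higher (3.8e-14), each against 0 counts in both libraries labelled sh-Ren with doxycycline. Insig1, a regulator of sterol synthesis, fell 9.77-fold (log2 fold change -3.29, SE 0.36, adjusted p = 1.25e-09, n = 2 per group). In all, 2490 of 8459 genes changed, 1233 higher and 1257 lower. Genes without opposite-strand overlap were 630 higher and 913 lower, and the uncertain overlapped genes 588 higher and 342 lower, while a fit of the genes without overlap alone gave 765 higher and 752 lower. Of the higher genes 109 had 0 counts in sh-Ren with doxycycline, and of the lower genes 134 had 0 in sh-EiF5A. The groups' libraries did not overlap for 61.1% of genes, against 33.3% by chance. Scaling by library totals moved the median of all genes by -1.69 and gave 204 genes higher and 4819 lower, so directions are given relative to that shift. At equal depth 1028 genes changed, 617 higher and 411 lower. The fit shared each gene's spread over all groups, while the sh-EiF5A replicates correlated least (Pearson r 0.8598). The edgeR p-values of this comparison may therefore be too small. With only the 4 libraries compared, 1755 of 6779 tested genes changed, 946 higher and 809 lower.

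Of 26 early B cell genes tested in sh-EiF5A, 21 rose, 0 fell and 5 did not pass, with 22 up adjusted over the list alone. The list median was 6.53, or 4.76 with the 13 members at 0 in a group set at their bound (camera adjusted p = 2.03e-17, and adjusted p = 0.0128 with an estimated correlation). Cd24a, a surface protein of B-cell precursors, rose by 4.73 (SE 0.32, adjusted p = 3.39e-15). Il7r, the interleukin 7 receptor, held 119 counts against 2, a ratio of 165 (95% counting interval 44.5 to 1374, adjusted p = 2.4e-13). Outside the lists, Cd53, a leukocyte membrane protein, was at least 189-fold higher (2.03e-15) and Pde2a, a phosphodiesterase, at least 171-fold higher (1.02e-15). Tsix was at least 3878-fold higher (4.25e-22) but is uncertain, since it overlaps Xist on the other strand. Summed over each list, early B genes held 2260 ± 134 CPM in sh-EiF5A, 1360 ± 170 in sh-Dhps, 111 ± 19.4 in sh-Ren with doxycycline and 138 ± 4.95 without it (SD, n = 2 each). Among the lowest genes, Macc1 (at least 25.9-fold lower, 1.07e-09), Crabp2, a retinoic acid carrier (at least 22.7-fold lower, 2.85e-08), and Cald1, an actin-binding protein (at least 11.3-fold lower, 6.17e-06), held 0 counts in sh-EiF5A. Dcn, a matrix proteoglycan, was at least 8.92-fold lower (2.35e-05), and Lum, another, held 1 count against 86, a ratio of 0.0321 (0.000805 to 0.184, 5.09e-05).

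**Figure D2:**
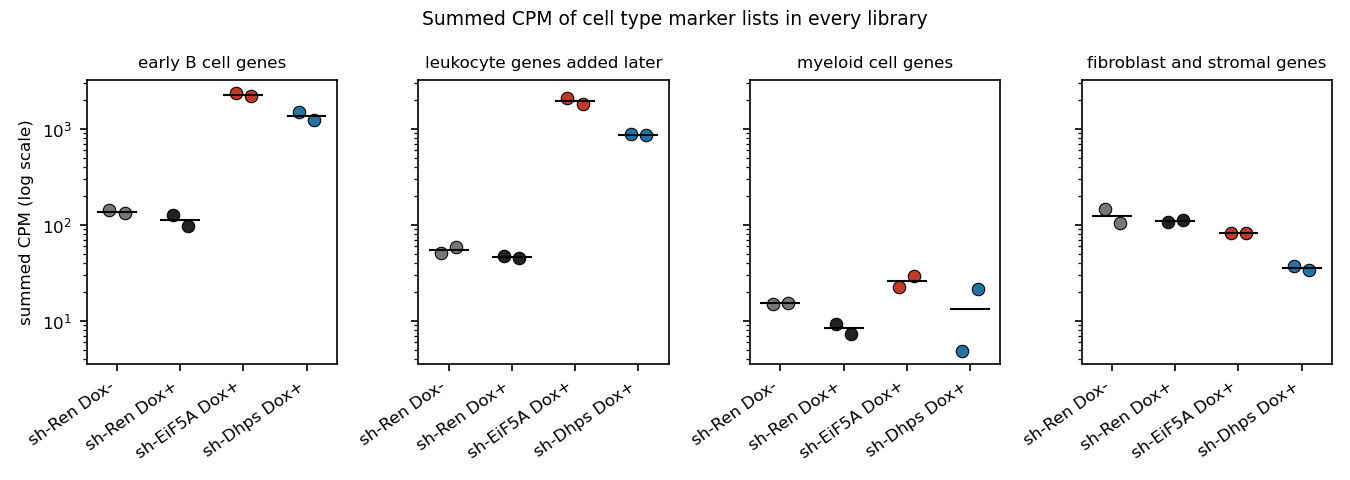
Summed CPM of the cell-type gene lists in each of the 8 libraries, as plotted on the axis scale, with 2 libraries per group. Early B cell genes averaged 2260 CPM in sh-EiF5A and 1360 in sh-Dhps, against 138 and 111 in the libraries labelled sh-Ren; scaled by library totals, which moves all genes by 1.82, the sh-Dhps against sh-EiF5A median has the opposite sign, and it is -0.461 less that shift.

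Summed CPM (mean ± SD, n = 2) of the other cell-type lists is given in the order sh-Ren without doxycycline, sh-Ren with it, sh-EiF5A and sh-Dhps. Fibroblast genes held 124 ± 29, 109 ± 2.83, 82.2 ± 1.13 and 35.4 ± 2.26. Myeloid genes held 15.2 ± 0.424, 8.38 ± 1.42, 26.2 ± 4.88 and 13.2 ± 11.8. Erythroid genes held 15.4 ± 5.8, 20.1 ± 2.97, 29.6 ± 12.5 and 8.5 ± 3.68. T and natural killer cell genes, mostly counts of the overlapped gene Cd247, held 289 ± 24, 330 ± 58.7, 562 ± 177 and 222 ± 21.2. Mature B cell genes held 58.4 ± 16, 60.6 ± 2.33, 164 ± 58 and 93.6 ± 2.05, and plasma cell genes 112 ± 3.54, 106 ± 4.24, 184 ± 30.4 and 212 ± 29.

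Of 31 histone genes tested in sh-EiF5A, 26 rose, 1 fell and 4 did not pass, with 26 up and 1 down adjusted over the list alone. Their median was 2.15 (camera adjusted p = 1.99e-11, and adjusted p = 0.107 with an estimated correlation). Hist1h1c rose by 3.50 (SE 0.31, 4.18e-12) and Hist1h1a by 3.13 (SE 0.31, 1.56e-10), both linker histones of chromatin. Of 76 ribosomal protein genes, 59 rose, 0 fell and 17 did not pass, with 61 up adjusted over the list alone, and their median of 1.12 became -0.478 when scaled by library totals (camera adjusted p = 2.44e-13, and adjusted p = 0.368 with an estimated correlation). Rpl18a rose by 2.53 (SE 0.26, 3.07e-10) and Rpl37 by 2.41 (SE 0.30, 2.2e-08), calls that ended with library totals (1.09, 0.0917 and 0.61, 0.322). Both groups are uncertain because of near-identical copies, and Rn45s and Lars2 took 81.35% and 47.55% of the counts in these libraries. Of 51 MYC-induced growth genes, 11 rose, 1 fell and 39 did not pass, with 10 up and 0 down adjusted over the list alone, and their median of 0.53 became -1.16 when scaled by library totals (camera adjusted p = 0.00718, and adjusted p = 0.363 with an estimated correlation). Sord, sorbitol dehydrogenase, rose by 3.01 (SE 0.44, 6.98e-07), and Pa2g4, a nucleolar growth regulator, by 1.21 (SE 0.26, 0.000422), or -0.31 scaled by library totals (0.625). Myc itself lay at 0.19 (SE 0.28, adjusted p = 0.662). The growth list lost its call without sh-Ren Dox+ replicate 1 (0.0565) or sh-EiF5A Dox+ replicate 1 (0.0608).

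Of 32 glycolysis and hypoxia genes in sh-EiF5A, 0 rose, 16 fell and 16 did not pass, with 1 up and 20 down adjusted over the list alone and a median of -1.01 (camera adjusted p = 0.000106, and adjusted p = 0.235 with an estimated correlation). Ero1l, an oxidase of protein folding, fell by 2.78 on the log2 scale (SE 0.32, 3.54e-09), P4ha1, a collagen prolyl hydroxylase, by 2.10 (SE 0.29, 3.32e-07), and Egln3, an oxygen sensor, lay at -3.12 (SE 0.47, 1.55e-06). Of 21 cholesterol synthesis genes, 0 rose, 11 fell and 10 did not pass, with 1 up and 13 down adjusted over the list alone and a median of -1.08 (camera adjusted p = 0.000734, and adjusted p = 0.107 with an estimated correlation). Hmgcr, the rate-limiting enzyme, fell by 1.82 (SE 0.34, 4.62e-05). Of 60 genes of G2/M and mitosis, 1 rose, 24 fell and 35 did not pass, with 2 up and 27 down adjusted over the list alone and a median of -0.713 (camera adjusted p = 0.000937, and adjusted p = 0.288 with an estimated correlation). Aspm, a spindle pole protein, lay at -1.87 (SE 0.30, 3.57e-06), Bub1, a checkpoint kinase, at -1.71 (SE 0.29, 1.06e-05) and Kif23, a motor of cell division, at -1.68 (SE 0.31, 4.71e-05), while Gas2l3, a cytoskeletal linker, rose by 1.61 (SE 0.27, 9.96e-06), a call that ended with library totals (0.26, 0.701). In the same libraries early B genes summed to 2260 CPM against 111.

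Of 11 polyamine and hypusine genes in sh-EiF5A, 3 rose, 2 fell and 6 did not pass, with 4 up and 2 down adjusted over the list alone (median -0.0998, camera adjusted p = 0.953). Mtap, which salvages the by-product of polyamine synthesis, fell by 3.01 on the log2 scale (SE 0.28, 2.48e-11). Odc1 rose by 0.84 (SE 0.26, 0.0122), or -0.80 scaled by library totals (0.205), and lost its call without sh-Ren Dox+ replicate 1 (0.262) or sh-EiF5A Dox+ replicate 1 (0.146). Slc7a11, the cystine transporter, held 2 counts against 188, a ratio of 0.0294 (0.00354 to 0.108, 5.22e-08), and Mcl1, a survival protein, fell by 1.66 (SE 0.29, 2.35e-05). The other 15 lists had camera adjusted p-values from 0.197 to 0.971. Among them, 2 of 25 p53 targets rose and 7 fell (median -0.855), and 4 of 31 integrated stress response genes rose and 11 fell (median -0.386). In the order risen, fallen and not past, unfolded protein response genes numbered 1, 6 and 22, lysosome genes 3, 8 and 22, mitochondrial chaperones 2, 2 and 13, BCL2 family genes 0, 1 and 6, and plasma cell genes 1, 1 and 4. Lists whose median turned negative when scaled by library totals were ribosome biogenesis with 7, 4 and 39, translation factors and tRNA synthetases 5, 5 and 38, G1/S and DNA replication 5, 2 and 50, interferon response 5, 1 and 10, oxidative phosphorylation 7, 8 and 45, mitochondrial ribosome 8, 3 and 51, and mature B cell genes 2, 0 and 3.

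In sh-Dhps libraries, genes of early B cells and histones were again higher than in libraries labelled sh-Ren with doxycycline, and genes of glycolysis and the hypoxia response were lower, by camera with its preset correlation. With an estimated correlation the early B call held (adjusted p = 0.00617), and the histone (0.102) and glycolysis (0.108) calls ended. Cd24a rose 22.3-fold (log2 fold change 4.48, SE 0.32, edgeR adjusted p = 3.18e-14, n = 2 per group), and Pou2af1, a coactivator of B-cell transcription, was at least 76.3-fold higher (6.17e-13). Ero1l fell 7.09-fold (log2 fold change -2.83, SE 0.27, 1.11e-10). In all, 1567 genes changed, 704 higher and 863 lower. Genes without opposite-strand overlap were 490 higher and 460 lower, and the uncertain overlapped genes 212 higher and 399 lower, while a fit of the genes without overlap alone gave 445 higher and 478 lower. Of all these, 109 of the higher genes had 0 counts in sh-Ren with doxycycline and 3 of the lower genes had 0 in sh-Dhps. The groups' libraries did not overlap for 61.3% of genes, against 33.3% by chance. With only the 4 libraries compared, so without the sh-EiF5A libraries in the shared spread, 1997 of 8032 tested genes changed, 914 higher and 1083 lower. The count was 929 without sh-Ren Dox+ replicate 1, 803 and 876 without sh-Dhps Dox+ replicate 1 and 2, 850 with DESeq2 and 383 with library totals, which moved the median of all genes by 0.126.

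Of 26 early B cell genes in sh-Dhps, 21 rose, 0 fell and 5 did not pass, with 23 up adjusted over the list alone. Their median was 6.49, or 3.94 with the 13 members at 0 set at their bound (camera adjusted p = 3.5e-25, and adjusted p = 0.00617 with an estimated correlation). Il7r held 255 counts against 2, a ratio of 87.4 (95% counting interval 23.9 to 725, 3.09e-11), and Vpreb3 was at least 38.6-fold higher (2.41e-10). Cd53 was at least 297-fold higher (4.71e-17), and Plcg2, a phospholipase of B-cell receptor signalling, at least 93.2-fold higher (2.12e-13). Tsix was at least 363-fold higher (4.71e-17) and uncertain. Early B genes summed to 1360 CPM against 111. Among the lowest genes, Crabp2 lay at -5.43 (SE 0.51, 1.02e-10), Flrt3, an adhesion protein, at -5.53 (SE 0.48, 6.08e-12), Cald1 at -4.67 (SE 0.59, 1.13e-07), Lum at -4.85 (SE 0.61, 9.11e-08) and Dcn at -2.27 (SE 0.48, 0.000473).

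Of 31 histone genes in sh-Dhps, 20 rose, 0 fell and 11 did not pass, with 24 up and 1 down adjusted over the list alone and a median of 1.86 (camera adjusted p = 2.59e-12, and adjusted p = 0.102 with an estimated correlation). Hist1h2bg rose by 4.04 (SE 0.53, 1.76e-07) and Hist1h1a by 2.28 (SE 0.30, 2.27e-07). Of 76 ribosomal protein genes, 27 rose, 3 fell and 46 did not pass, with 31 up and 5 down adjusted over the list alone and a median of 0.488 (camera adjusted p = 0.000208, and adjusted p = 0.677 with an estimated correlation). Rpl27 rose 2.30-fold (SE 0.25 on the log2 scale, 0.000507) and Rpl38 by 1.15 on that scale (SE 0.26, 0.001), changes that kept their size with library totals (1.34 and 1.28) but did not pass (0.21 and 0.214). Both groups are uncertain because of near-identical copies. In this comparison general leukocyte genes also went from 46.4 to 869 CPM and fibroblast genes from 109 to 35.4. Of 51 MYC-induced growth genes, 12 rose, 1 fell and 38 did not pass, with 14 up and 1 down adjusted over the list alone and a median of 0.50 (camera adjusted p = 0.00123, and adjusted p = 0.347 with an estimated correlation). Ddx18, a nucleolar helicase, rose by 1.19 (SE 0.27, 0.00128), which did not pass with library totals (1.32, 0.18) or at equal depth (0.96, 0.199), and Utp20, a small-subunit processing factor, by 1.16 (SE 0.26, 0.00121), a call that ended without sh-Ren Dox+ replicate 1 (0.0782), with library totals (1.265, 0.218) and at equal depth (1.17, 0.0921). Of 50 ribosome biogenesis genes, 8 rose, 1 fell and 41 did not pass, with 8 up and 1 down adjusted over the list alone and a median of 0.284 (camera adjusted p = 0.0367, and adjusted p = 0.587 with an estimated correlation). Nat10, an RNA acetyltransferase, rose by 1.74 (SE 0.37, 0.000491), a call that ended at equal depth (1.00, 0.461), and Polr1b, a subunit of RNA polymerase I, by 1.26 (SE 0.31, 0.003), a call that ended without sh-Ren Dox+ replicate 1 (0.0957), with DESeq2 (0.0593), with library totals (1.365, 0.211) and at equal depth (0.92, 0.339). The biogenesis call ended without sh-Ren Dox- replicate 1 (0.0619) or 2 (0.0626), sh-Ren Dox+ replicate 2 (0.115) or sh-Dhps Dox+ replicate 2 (0.0992), and without overlapped genes (0.0875). Myc lay at -0.64 (SE 0.26, adjusted p = 0.0842) and passed without sh-EiF5A Dox+ replicate 1 (0.0457) or 2 (0.0472) or sh-Ren Dox+ replicate 2 (0.039), and with only the 4 libraries compared (0.032).

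Of 32 glycolysis and hypoxia genes in sh-Dhps, 1 rose, 17 fell and 14 did not pass, with 1 up and 19 down adjusted over the list alone and a median of -1.15 (camera adjusted p = 1.53e-08, and adjusted p = 0.108 with an estimated correlation). P4ha1 lay at -2.27 (SE 0.26, 1.03e-08) and Egln3 at -2.55 (SE 0.33, 1.66e-07). In the same comparison early B genes went from 111 to 1360 CPM, general leukocyte genes from 46.4 to 869 and fibroblast genes from 109 to 35.4. Of 11 polyamine and hypusine genes, 3 rose, 2 fell and 6 did not pass, with 4 up and 2 down adjusted over the list alone (median 0.392, camera adjusted p = 0.341). Odc1 rose by 1.05 (SE 0.25, 0.00246), a call that ended without sh-Ren Dox+ replicate 1 (0.141) and with library totals (1.15, 0.306), and Mtap lay at -1.59 (SE 0.24, 3.51e-06), a call that ended with library totals (-1.47, 0.156). The other 16 lists had camera adjusted p-values from 0.0745 to 0.995. Among them, 2 of 60 genes of G2/M and mitosis rose and 9 fell, including Kif23 at -1.27 (SE 0.25, 0.000228) and Aspm at -1.22 (SE 0.25, 0.000264), calls that ended with library totals (-1.15, 0.286 and -1.09, 0.34) and, for Kif23, at equal depth (-0.93, 0.128). Perp, a p53 target of cell adhesion, rose by 2.09 (SE 0.36, 3.01e-05), as the only riser of 25 p53 targets, of which 5 fell. Of 33 lysosome genes 5 rose and 0 fell. Lamp1 of the lysosomal membrane rose by 1.70 (SE 0.25, 2.46e-06) but is overlapped by Grtp1 and uncertain, and Psap, a lysosomal lipid-handling protein, rose by 1.19 (SE 0.29, 0.0027), a call that ended without sh-Ren Dox+ replicate 1 (0.0676) or sh-Dhps Dox+ replicate 2 (0.137), with DESeq2 (0.0509), with library totals (1.31, 0.191) and at equal depth (1.35, 0.0944). In the order risen, fallen and not past, cholesterol synthesis genes numbered 0, 2 and 19, integrated stress response genes 4, 4 and 23, unfolded protein response genes 3, 3 and 23, translation factors and tRNA synthetases 6, 3 and 39, and G1/S genes 3, 2 and 52. Oxidative phosphorylation genes numbered 4, 2 and 54, mitochondrial ribosome genes 4, 2 and 56, mitochondrial chaperones 1, 1 and 15, interferon response genes 2, 2 and 12, BCL2 family genes, whose median reversed when scaled by library totals, 0, 0 and 7, mature B cell genes 2, 1 and 2, and plasma cell genes 1, 0 and 5.

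Against the same libraries labelled sh-Ren with doxycycline, 813 genes changed in the same direction in sh-EiF5A and sh-Dhps, 421 higher and the rest lower, and 84 in opposite directions. Among the shared genes, Cd53, Pde2a and Plcg2 stood among the highest and Crabp2, Lum and Cald1 among the lowest. Lists of the same sizes drawn independently would share 102.6 higher and 128.2 lower genes, and simulated unchanged groups against the same 2 control libraries shared 0 in 50 draws. Groups simulated as unchanged leave few genes to call, so this 0 does not tell how many of the 813 come from the shared controls. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.695 against 0.413 in the simulation, and a covariance of 1.773 against 0.103, a difference of 1.67. The same sign held for 64.55% of genes, against 64.6% (63.5% to 66.2%) in the simulation. With separate controls the count was 726 or 712, and with the same controls it was 474 with DESeq2, 306 with library totals and 236 at equal depth. The 2 control libraries were not split between the depletions, so part of the excess may come from them. A different source of cells in the libraries labelled sh-Ren, where general leukocyte genes stood at 5.84% of the sh-Dhps rate, could produce such sharing as well, so it is not shown to be an effect of the depletions. The count was 515 and 516 without sh-Dhps Dox+ replicate 1 and 2.

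Compared directly, sh-Dhps libraries held higher lysosome, cholesterol synthesis and mitosis genes than sh-EiF5A libraries, and lower early B cell, ribosomal protein and histone genes, the last 3 of which changed sign when scaled by library totals, with a shift of all genes by 1.82, and kept it less that shift (medians -0.461, -0.804 and -0.617). These list calls come from camera with its preset correlation and all ended with an estimated correlation (adjusted p = 0.301 for lysosome, cholesterol synthesis and early B genes, 0.615 for the other 3), and 52 of 60 mitosis genes did not pass. Psap was 4.95-fold higher (log2 difference 2.31, SE 0.39, edgeR adjusted p = 1.4e-05, n = 2 per group), and Rag1 10.3-fold lower (-3.37, SE 0.36, 3.39e-09). In all, 1952 genes differed, 837 higher and 1115 lower in sh-Dhps. Genes without opposite-strand overlap were 622 higher and 436 lower, and the uncertain overlapped genes 215 higher and 660 lower, while a fit of the genes without overlap alone gave 424 higher and 529 lower. The median difference was 0.28 in genes without overlap and -0.266 in genes overlapped over at least 200 bases. By counts, 63 of the higher genes were at 0 in sh-EiF5A. General leukocyte genes summed to 869 CPM in sh-Dhps, between 46.4 in sh-Ren with doxycycline and 1960 in sh-EiF5A. The groups may therefore differ in their cells, so the list differences are not shown to be effects of the depletions. The groups' libraries did not overlap for 61.9% of genes, against 33.3% by chance. Library totals moved the median of all genes by 1.82 and gave 5516 genes higher and 38 lower. The count was 1197 without sh-Dhps Dox+ replicate 1.

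Of 33 lysosome genes, 12 were higher, 3 lower and 18 not past the threshold, with 13 higher and 3 lower adjusted over the list alone and a median of 0.616 (camera adjusted p = 0.0249, and adjusted p = 0.301 with an estimated correlation). Lamp2, a lysosomal membrane protein, was higher by 1.73 (SE 0.33, 0.000128) and Atp6v1a, of the proton pump, by 1.49 (SE 0.30, 0.0002), while Ctsa (2.03, SE 0.33, 7.06e-06) is overlapped by Pltp and uncertain. Of 21 cholesterol synthesis genes, 8 were higher, 0 lower and 13 not past, with 10 higher adjusted over the list alone and a median of 0.719 (camera adjusted p = 0.0244, and adjusted p = 0.301 with an estimated correlation). Insig1 was higher by 1.72 (SE 0.38, 0.00072), and Hmgcs1 (1.73, SE 0.38, 0.000736) is overlapped and uncertain. Of 60 genes of G2/M and mitosis, 6 were higher, 2 lower and 52 not past, with 2 higher and 2 lower adjusted over the list alone and a median of 0.549 (camera adjusted p = 0.0401, and adjusted p = 0.615 with an estimated correlation). Kif11, a spindle motor, was higher by 0.85 (SE 0.26, 0.0132), a call that ended without sh-EiF5A Dox+ replicate 2 (0.051) or sh-Dhps Dox+ replicate 1 (0.125) and at equal depth (0.64, 0.163). Ccna2, a cyclin, was lower (-1.14, or 0.40 scaled by library totals, SE 0.27, 0.00141), is overlapped by Exosc9 and uncertain, and lost its call without sh-Dhps Dox+ replicate 2 (0.0633). The mitosis list lost its call without sh-EiF5A Dox+ replicate 2 (0.231) or sh-Dhps Dox+ replicate 1 (0.0736) and without overlapped genes (0.257), and the cholesterol list without sh-EiF5A Dox+ replicate 2 (0.101) and without overlapped genes (0.156). Rn45s and Lars2 took 22.17% and 22.33% of the counts in sh-Dhps against 81.35% and 47.55% in sh-EiF5A.

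Of 76 ribosomal protein genes, 1 was higher in sh-Dhps, 39 lower and 36 not past, with 1 higher and 44 lower adjusted over the list alone, and their median of -0.682 became 1.01 when scaled by library totals (camera adjusted p = 1.67e-08, and adjusted p = 0.615 with an estimated correlation). Rpl18a lay at -1.68 (SE 0.25, 1.74e-06) and Rpl13a at -1.32 (SE 0.26, 0.00017), or -0.13 (0.852) and 0.45 (0.466) scaled by library totals. Of 31 histone genes, 1 was higher, 8 lower and 22 not past, with 1 higher and 9 lower adjusted over the list alone, and their median of -0.57 became 1.2 when scaled by library totals (camera adjusted p = 0.0292, and adjusted p = 0.615 with an estimated correlation). Hist1h1c lay at -1.71 (SE 0.26, 3.01e-06) and Hist1h1e at -1.59 (SE 0.27, 1.77e-05), or 0.0016 and 0.16 scaled by library totals. The histone call ended without sh-EiF5A Dox+ replicate 1 (0.0985). Of 26 early B cell genes, 0 were higher, 8 lower and 18 not past, with 8 lower adjusted over the list alone, and their median of -0.663 became 1.35 when scaled by library totals (camera adjusted p = 0.0244, and adjusted p = 0.301 with an estimated correlation). Vpreb3 lay at -1.77 (SE 0.31, 3.6e-05), or -0.18 (0.792) scaled by library totals. Cd19, a B-cell surface protein, lay at -1.77 (SE 0.43, 0.00191), or 0.037 (0.96) scaled by library totals, a call that also ended without sh-EiF5A Dox+ replicate 1 (0.0589) and at equal depth (0.205).

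Outside these lists, Pten, a phosphatase that restrains growth signalling, was lower in sh-Dhps than in sh-EiF5A (-5.17, SE 0.56, 4.01e-09), as were Enox2, an oxidase (-4.01, SE 0.37, 1.48e-10), and Gimap6, a lymphocyte GTPase (-3.70, SE 0.37, 8.57e-10). Laptm4b, a lysosomal membrane protein, was at least 8.51-fold higher (0.000335), Myo6, a motor protein, at least 5.70-fold (0.000317) and Emp2, a membrane protein, at least 4.63-fold (0.00059), each against 0 counts in sh-EiF5A. Dcn was at least 1.82-fold higher (0.0278), a call that ended without sh-EiF5A Dox+ replicate 1 (0.149) or 2 (0.0873) or sh-Dhps Dox+ replicate 2 (0.0764), with DESeq2 (0.0831) and at equal depth (adjusted p of 1). In the 4 libraries labelled sh-Ren together, Myo6 held 172 counts, Emp2 151 and Dcn 144. The scaled counts in sh-Dhps were 0.538, 0.497 and 0.205 of those, so these genes are not shown to differ because of the depletions. Perp was higher by 3.88 (SE 0.57, 1.24e-06) and Mcl1 by 1.56 (SE 0.29, 7.78e-05), while Trp53inp1, a p53 target, was lower (-3.01, SE 0.37, 4.62e-08). Slc7a11 held 111 counts against 2, a ratio of 13.8 (3.72 to 115, 0.000142). Yme1l1, a mitochondrial protease, was higher by 1.68 (SE 0.31, 6.02e-05) and Hspa9, a mitochondrial chaperone, by 0.93 (SE 0.25, 0.00485). Mtap was higher by 1.43 (SE 0.28, 0.000134) and Odc1 differed by 0.21 (SE 0.25, adjusted p = 0.596). Odc1 passed with library totals (1.95, 0.0038), which moved all genes by 1.82, so most of that value is the shift. The polyamine list had 2 higher, 1 lower and 8 not past, with 3 higher and 1 lower adjusted over the list alone (median 0.444, camera adjusted p = 0.277). B2m, of antigen presentation, was lower (-0.78, or 0.83 scaled by library totals, SE 0.26, 0.0241), a call that ended without sh-EiF5A Dox+ replicate 1 (0.0542) or 2 (0.101) or sh-Dhps Dox+ replicate 2 (0.314), with DESeq2 (0.0532), no filter (0.134), the CPM filter (0.0639) and at equal depth (0.261). Myc was lower (-0.83, or 0.69 scaled by library totals, SE 0.28, 0.0284), a call that ended without sh-EiF5A Dox+ replicate 2 (0.323) or sh-Dhps Dox+ replicate 1 (0.28) or 2 (0.0531), with DESeq2 (0.0654), no filter (0.127), the CPM filter (0.0633), a minimum change of 1.2-fold (0.0534) and at equal depth (0.293). The other 16 lists had camera adjusted p-values from 0.142 to 0.843. In the order higher, lower and not past, MYC-induced growth genes numbered 1, 6 and 44, ribosome biogenesis 2, 1 and 47, translation factors and tRNA synthetases 5, 3 and 40, p53 targets 2, 2 and 21, integrated stress response 5, 2 and 24, and unfolded protein response 2, 1 and 26. Oxidative phosphorylation genes numbered 9, 1 and 50, mitochondrial ribosome 4, 6 and 52, mitochondrial chaperones 2, 1 and 14, glycolysis 0, 4 and 28, BCL2 family 1, 0 and 6, mature B cell genes 0, 0 and 5, and plasma cell genes 0, 0 and 6. G1/S genes (4, 4 and 49) and interferon response genes (0, 3 and 13) had medians that reversed when scaled by library totals.

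**Figure D3:**
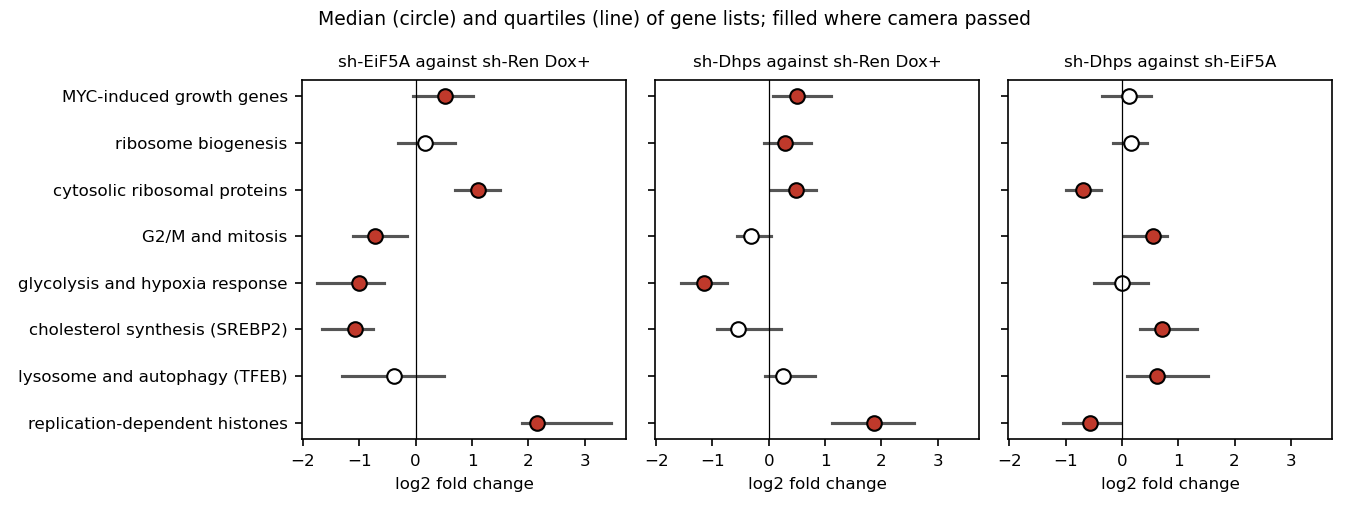
Median (circle) and quartiles (line) of the log2 fold changes of gene lists that camera called in any comparison drawn, each of 2 against 2 libraries. The comparisons are sh-EiF5A and sh-Dhps, each against sh-Ren with doxycycline, and sh-Dhps against sh-EiF5A. Filled circles mark calls by camera with its preset correlation. The early B cell list is not drawn, and its medians are given here in words only. Early B cell genes lay at 6.53 in sh-EiF5A and 6.49 in sh-Dhps, histones at 2.15 and 1.86, and glycolysis genes at -1.01 and -1.15; scaled by library totals, the sh-EiF5A medians of ribosomal protein and MYC-induced growth genes, and the sh-Dhps against sh-EiF5A medians of ribosomal protein, histone and early B cell genes, change sign with shifts of all genes by -1.69 and 1.82, and keep it less these shifts (1.21, 0.53, -0.804, -0.617 and -0.461).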

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

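All tests of explanations in this part were chosen after the results were seen, except the removal of the length and GC trend. Each result here differed between the depletions in the direct test of sh-Dhps against sh-EiF5A, the lists by camera with its preset correlation only. With an estimated correlation 0 lists were called (adjusted p = 0.301 for lysosome, cholesterol synthesis and early B genes, 0.615 for the other 3). The medians of the lists were -0.682 for ribosomal proteins, 0.549 for G2/M and mitosis, 0.719 for cholesterol synthesis, 0.616 for lysosome and autophagy, -0.57 for histones and -0.663 for early B cell genes, of which the ribosomal protein, histone and early B medians change sign with library totals, which move all genes by 1.82, and keep it less that shift (-0.804, -0.617 and -0.461). The gene Eif5a differed by 4.21, Dhps by -2.4 and Myc by -0.833, of which the Dhps difference lost its call with library totals (-0.8106, adjusted p = 0.295) and at equal depth (-1.048, 0.358), and Myc changes sign with library totals by less than that shift.

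Most leukocyte genes were near 0 in the 4 libraries labelled sh-Ren, which set the size of the early B cell changes. Exceptions included Sox4 (23, 53, 27 and 22 counts), and Ptpn6 (12, 22, 17 and 22), Cd22 (19, 16, 46 and 12) and Cd247 (216, 419, 413 and 339), of which the last 3 are overlapped and uncertain. Depth was argued against: early B genes without overlap held 283 counts there, 5.06% of the 5596 the sh-Dhps rate would give. These genes share no annotated exon with the other strand, so exonic reads of annotated genes there cannot make the split. The 18 tested members had a median of 7.33 (95% bootstrap interval over genes 5.61 to 7.84) in sh-Dhps against sh-Ren with doxycycline. That median cannot tell on which strand reads were counted, since opposite-strand counting would make these counts uncertain too. Of the 26 tested early B genes 13 were at 0 in a group, so they passed the filter through the groups where they were high. Cells other than leukocytes in the libraries labelled sh-Ren are a candidate explanation, because 37 general leukocyte genes held 238 counts against 4073 at the sh-Dhps rate, or 5.84%; without the 8 genes whose counts had been seen before, the share was 9.16% over 29 genes. Cd53 held 1, 0, 0 and 0 counts in the libraries labelled sh-Ren. Ptprc, a leukocyte surface protein, held 0 in each, against 75 and 50 in sh-EiF5A and 117 and 100 in sh-Dhps. Xist, which is not a leukocyte gene, was split the same way, as given below. The libraries labelled sh-Ren carry no EiF5A or Dhps hairpin, so cells of a B-lineage tumour in them would be undepleted leukocytes. Those without doxycycline held 127 counts of the general leukocyte genes. As sets, the 5.84% for general leukocyte genes and 5.06% for early B genes argue against a rise by depletion as the whole cause. A part played by depletion cannot be told apart from a different source of cells, since hairpin and library are the same split. Changes against the libraries labelled sh-Ren are therefore not shown to be effects of the depletions.

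Ribosomal protein and histone genes were higher in sh-EiF5A than in sh-Dhps libraries by camera with its preset correlation, and both calls ended with an estimated correlation (adjusted p = 0.615 each). Exonic length and GC content were argued against as the whole cause for ribosomal proteins, whose median kept most of its size (-0.672 before and -0.509 after the trend was removed, camera adjusted p = 1.87e-05 with the preset correlation). For histones the same removal took the median from -0.492 to -0.211, with an interquartile range of 1.06 before and 1.1 after, and the call ended (adjusted p = 0.301) because the median shrank, so length and GC may account for much of it. Rn45s and Lars2 taking most of the counts stays open: the median of ribosomal protein genes without them was -0.66, but TMM trims both genes in all 56 pairs of libraries, so their removal could hardly move it. Relative to other genes the 2 medians kept their sign under RLE (-0.757 and -0.644), upper-quartile (-0.686 and -0.571) and DESeq2 scaling (-0.697 and -0.599), and under library totals less the shift of all genes (-0.804 and -0.617). Against sh-Ren with doxycycline, the TMM-scaled medians were 0.488 and 1.86 in sh-Dhps, below 1.12 and 2.15 in sh-EiF5A. General leukocyte genes in sh-Dhps lay between those groups as well. Depletion itself, near-identical copies and a difference in cells between the groups stay open as untested.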

How the results depend on the processing

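Leaving out genes overlapped on the other strand, leaving out Rn45s and Lars2, and equal depth were chosen after the data were seen, and the rest before. Of 106 gene results, 74 kept their direction and side of the threshold under every alternative. Across gene results and alternatives, 2472 values did so, 61 lost the call, 10 gained it, 9 changed sign and 1 fell to 0; across list results 200 kept the call and 40 did not, of which 5 were by fry, which tests a list against no change and so does not bear on a difference from other genes. Library totals gave 5023 changed genes in sh-EiF5A (4.06% higher, against 49.5%), 383 in sh-Dhps (59.8% higher, against 44.9%), 5554 between the depletions (99.3% higher, against 42.9%), 306 shared, and a Dhps change of -1.66. They changed the sign of Odc1 (-0.80) and Pa2g4 (-0.31) in sh-EiF5A, and Myc (0.69), Rpl13a (0.45), Hist1h1c (0.0016), Hist1h1e (0.16), Ccna2 (0.40), Cd19 (0.037) and B2m (0.83) between the depletions, by less than the shifts of all genes (-1.69 and 1.82), so these genes keep their sign relative to others. Equal depth, with fewer counts, gave 1028 in sh-EiF5A (60% higher), 414 in sh-Dhps, 775 between them (29.5% higher), 236 shared, a Dhps change of -0.80 and a Dcn difference of 0. Testing fewer genes, those without overlap, gave 1517, 923 and 953. DESeq2 gave 850 in sh-Dhps and 474 shared. With only the 4 libraries compared, the counts were 1755 in sh-EiF5A, 1997 in sh-Dhps, 1796 between them and 673 shared. For doxycycline no filter gave 6 genes, the CPM filter 6 and robust spread 4. Of the list tests, an estimated correlation left 0 for doxycycline, 1 for sh-EiF5A, 1 for sh-Dhps and 0 between them, and fry gave 0 for doxycycline and 14 for sh-EiF5A. Leaving out each library gave 0 to 7 genes for doxycycline, 1892 to 2644 for sh-EiF5A, 803 to 1961 for sh-Dhps, 1197 to 2166 between them and 515 to 847 shared, 0 to 2 lists for doxycycline, Dhps at -2.00 to -1.55 and Eif5a at -4.65 to -3.62; the lone library of a group is then assumed to vary like the others. Beyond fewer genes, counts or libraries, the cause was not tested. With the replicate number as a block the counts were 0, 2497, 1604 and 1990, with 830 shared and 1, 7, 6 and 6 lists called. Deviations of same-numbered libraries correlated at -0.0581 to 0.138. These values show no strong pairing by number, though counting noise at this depth could hide a weaker one.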

Other observations

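All tests in this part were chosen after the result was seen, except that of counting without strand, and the genes named were chosen after their values were seen. Counts of some further genes differed strongly between groups. Counts are given for the 2 libraries of sh-Ren without doxycycline, sh-Ren with it, sh-EiF5A and sh-Dhps, in that order. Xist, the RNA of X inactivation, held 0, 2, 4, 1, 576, 376, 1233 and 859 counts, though it overlaps Tsix and is uncertain. Spp1, a secreted phosphoprotein, held 312, 318, 323, 382, 1, 0, 54 and 37. Pten held 0, 3, 2, 1, 56, 29, 5 and 4. The cell-cycle inhibitors Cdkn2a and Cdkn2b held 0, 0, 0, 0, 8, 3, 1 and 10, and 0, 0, 0, 0, 20, 15, 4 and 0. E2f1, which was not tested, held 3, 9, 8, 6, 2, 4, 7 and 6. Cd19, Cd79a and Cd79b held 0 counts in all 4 libraries labelled sh-Ren. For 24 genes without overlap, with 0 counts in sh-EiF5A and at least 100 counts in those 4 libraries together, the ratio of the scaled count in sh-Dhps to that in sh-Ren ran from 0.0271 to 0.697 with a median of 0.209, and the 95% exact intervals of 17 left out the median; a first form of this comparison had used sh-Ren with doxycycline only.

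High counts appeared in genes that lie opposite an expressed gene, as in Snx22 with 47311 counts against 1339 in Ppib, and Ccdc38 with 63453 against 1341 in Snrpf. Counting on the strand opposite to the transcript is a candidate explanation: across genes, which are not independent replicates, counts correlated at a Spearman rho of 0.464 over 1190 overlapping pairs and 0.222 over 1344 neighbouring pairs, a difference of 0.242 (95% bootstrap interval 0.176 to 0.313). Counting without strand stays open, since the partner held more counts for 4 of 23 listed genes, or 17.4% (95% exact interval 4.95 to 38.8), on both sides of the bound set beforehand. Of the 100 genes with the most counts, 46.5% of those annotated were overlapped, against 35.4% of tested genes. Overlapped genes took 45.27% and 50.64% of the counts outside Rn45s and Lars2 in sh-EiF5A, against 35.88% to 42.05% elsewhere. If reads were counted on the opposite strand, genes without overlap are uncertain too. No biological explanation was tested.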
